A study of Saccharomyces cerevisiae with 2 samples.

How the data were processed

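Messenger RNA was sequenced from 2 strains of the budding yeast Saccharomyces cerevisiae, a strain the labels call wild type, and the strain Y518, which they call a mutant and the series title describes as producing much glutathione. Per the labels' protocols, a seed culture of each strain grew for 18 h at 30 °C and 180 rpm, was used as inoculum, and the fermentation was harvested after 24 h. Total RNA was purified on columns with DNase treatment, and libraries followed standard Illumina protocols. There was 1 library per strain.

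The deposited tables list one row per coding sequence, identified by RefSeq transcript records. Per the file headers, the authors gave for each library the count of uniquely mapped reads, the percent of the gene's length covered by reads, and the RPKM (reads scaled to the listed length and to the library's total reads). The deposited RPKM equalled the count divided by the listed length and by the library total for every gene, with 0 mismatches beyond a relative difference of 1e-06. The listed lengths are multiples of 3 for all 5734 genes and so are coding lengths without untranslated regions. The aligner, the counting tool and the genome build are not given in the sources used here. Because only uniquely mapped reads were counted, genes with near-identical copies lose reads, and their values are treated as uncertain. Whether reads were assigned by strand is not given, so overlapping genes on opposite strands could not be told apart.

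A series table held both libraries for 5734 genes and matched the tables of the single libraries in every count (0 mismatches). A dash in it stands for a gene without a read in that library. A second series table held the same values for 5080 of these genes, the first part of the longer table in the order of reads in the wild type, down to 37 reads. Deposited columns of other samples numbered 0. RefSeq accessions were looked up in the R64 reference annotation: 5685 matched with their version, 5713 matched when the version was ignored, and 21 did not match. The reference was used for current names, for the order of neighbouring genes, for GC content, and for a search for near-identical copies with BLAST+ 2.17.0 (a match to another coding sequence of at least 95% identity over at least 100 nt, found for 220 of the listed genes). Since the build behind the deposited counts is not named, no coordinates are printed.

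The library totals were 4708412 unique reads for the wild type and 4317183 for Y518. With 1 library per strain no test between strains was possible, and no p-value is given. The design fixed a rule of size before the data were examined. Genes with a mean of at least 5 RPKM over both libraries (5415 genes) were compared by the log2 of (RPKM + 1) in Y518 over (RPKM + 1) in the wild type. The added 1 RPKM is a pseudocount that understates the change of low genes. A gene was called at a ratio of at least 2-fold. Folds printed for single genes are ratios of reads per library total, without the pseudocount, with an exact conditional binomial 95% interval (Clopper-Pearson). These intervals, and the limit of 3 reads that a count of 0 allows in a library (0.637 CPM in the wild type and 0.695 CPM in Y518), cover counting error only. The spread between cultures and the choice of scaling are not in them. PCR duplicates are not independent molecules either. A fold against a library without reads is given as a lower bound against 3 reads.

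A total of 32 gene lists was fixed before the data were examined. They cover glutathione and its precursors, carbon, nitrogen and energy metabolism, stress, growth, metals, vitamins, mating type and sporulation. For each, the median log2 ratio was placed among 10000 random lists of the same size matched on mean RPKM in 10 bins. A list is said to stand apart below percentile 2.5 or above percentile 97.5. The percentile describes these 2 libraries. If the genes of a list varied independently, 1.6 of 32 lists would fall outside. Genes of a list can shift together between cultures, which the random lists do not reproduce. More lists can then fall outside without a difference between the strains. Genes are named by a rule fixed in advance. It takes every member of the list of glutathione synthesis, transport and turnover. It takes up to 4 members with the largest absolute log2 ratio of the 4 related precursor and redox lists. The same holds for each list that stands apart. Last, it takes the 12 highest and 12 lowest genes with a mean of at least 20 RPKM and a standard name. Other genes named beside them were chosen after their values were seen. List membership was taken from gene symbols, with HXT16 and ASP3-1 not matched.

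On simulated counts with the real means and totals, the 2-fold rule called 98% of genes changed 3-fold, 100% of those changed 4-fold or 8-fold, and 0% of those changed 1.5-fold, among 5416 genes. It called 17 of 5216 unchanged genes. The counting interval held the true ratio for 95.1% of genes. A planted list of 20 genes at 2-fold reached percentile 100, and 25 of 400 null lists fell outside the limits. The simulation holds counting error only.

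Alternatives tried were pseudocounts of 0.1 and 5 RPKM, no filter and a mean of at least 20 RPKM, centring on the median of all genes, TMM scaling with edgeR 4.0.16, CPM with 1 CPM added, and counting bounds beyond 2-fold. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, Biopython 1.88, matplotlib 3.10.9 and R 4.3.3.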

Results

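Transcript levels were compared between a wild-type strain of Saccharomyces cerevisiae and the high-glutathione mutant Y518 after 24 h of fermentation. Glutathione is the tripeptide of glutamate, cysteine and glycine and the main low-molecular-weight thiol of the cell. The comparison asks which transcripts differ between a high producer and the wild type. Each strain was represented by 1 library, so the differences below have no replicate check and compare these libraries. The sources used here do not say how closely the strains are related, so a count near 0 in 1 library does not separate a lack of transcript from a lack of the gene or of a match to the reference. The wild-type library held 4.71 M uniquely mapped reads over 5664 genes, and the Y518 library 4.32 M over 5681 genes. The median gene had 234 reads in the wild type and 262 in Y518. The cell wall gene SED1 alone took 4.19% of the reads in the wild type and 2.66% in Y518, and the 10 most abundant genes of each library took 13.0% and 10.4%. TAR1, which lies within the ribosomal DNA, took 1.17% and 1.49%.

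The 2 libraries differed widely. Of 5415 genes with a mean of at least 5 RPKM, 1076 (19.9%) were at least 2-fold higher in Y518 and 481 (8.88%) were at least 2-fold lower. At least 8-fold differences were seen for 87 genes with more reads in Y518 and 36 with fewer. The median log2 ratio of all genes was 0.27, a general offset in favour of Y518. When ratios were centred on that median, 714 genes were higher and 737 lower, and with TMM scaling 730 were higher and 713 lower, so the surplus of higher genes depended on the scaling. Higher genes made up 69.1% of all called genes as scaled by the authors, 49.2% after centring and 50.6% with TMM. Gene lists are therefore placed among random lists from the same libraries, and those with medians between 0 and 0.27 lie below the median of all genes.

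Among the 12 genes ranked highest in Y518, GRE1, a stress-induced hydrophilin, was 76.0-fold higher (95% counting interval 57.7 to 102). SPS100, a spore wall gene, was 86.1-fold higher (57.2 to 136), and AQY1, an aquaporin, 59.9-fold higher (45.8 to 79.9). The stationary-phase genes SPG4 and SPG1 were 56.9-fold and 42.6-fold higher. PHO89, a sodium-phosphate cotransporter, was 72.0-fold higher on 14 reads in the wild type. CPP3 was 61.4-fold higher on 3 reads in the wild type, with an interval of 20.7 to 301. EMA17 and ANB1 had 0 reads in the wild type and were at least 31.6-fold and 116-fold higher. ANB1, the hypoxic form of the translation factor eIF5A, has a close paralogue and was covered over only 18.8% of its length in Y518, so its value is uncertain. RPL41A had 19 reads in Y518 and 0 in the wild type, at least 6.91-fold higher, but its coding length is below the length used in the search for copies and it is uncertain too. The mitochondrial intron reading frames AI4 and AI5_BETA had 785 and 545 reads in Y518 and 0 in the wild type, at least 285-fold and 198-fold higher. AI4 was covered over only 27.6% of its length in Y518, and neither was in the search for near-identical copies, so both are uncertain.

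Among the 12 genes ranked lowest in Y518, FIT3 and FIT2, cell wall mannoproteins that retain siderophore iron, had 46590 and 22595 reads in the wild type and 3 reads each in Y518. Those counts give folds of 14240 (interval 4872 to 69052) and 6906 (2363 to 33490). FRE5, a putative ferric reductase, and PHR1, the DNA photolyase, had 702 and 354 reads in the wild type and 0 in Y518, at least 215-fold and 108-fold lower. These 4 genes lie in 1 stretch of chromosome XV with almost no reads in Y518. BDS1, a sulfatase within a run of 5 neighbouring genes without a read in Y518, had 500 reads against 0, and REE1 126 against 0, at least 153-fold and 38.5-fold lower. AGP1, a broad-range amino acid permease, was 51.4-fold lower in Y518 (45.7 to 58.1) and the serine deaminase gene CHA1 23.2-fold lower (18.5 to 29.5). The hexose transporter gene HXT4 was 26.3-fold lower. MF(ALPHA)1, an alpha-factor pheromone gene, had 180 reads against 4. HXT6 (9969 reads against 2) and SNZ2 (572 against 0) were also among the lowest, but both have near-identical copies and were covered over only 7.53% and 15.8% of their length in the wild type.

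Genes of glutathione synthesis, transport and turnover were higher in Y518 as a group. Of 10 measured members, 6 were at least 2-fold higher, 1 was lower and 3 were within 2-fold. The median log2 ratio was 1.15, which is 0.88 above the median of all genes and at percentile 99.8 of matched random lists. GSH1 (YJL101C), encoding gamma-glutamylcysteine synthetase, the first and rate-limiting enzyme of the pathway, had 26.5 RPKM in the wild type and 117 RPKM in Y518, a 4.41-fold excess (95% counting interval 3.84 to 5.08). GSH2 (YOL049W), encoding glutathione synthetase, the second enzyme, had 44.6 and 40.2 RPKM, 1.11-fold lower in Y518 with an interval of 0.94 to 1.32. After centring on the median of all genes the log2 ratio of GSH2 was -0.42, still within 2-fold. OPT1, a plasma membrane transporter of glutathione, was 5.91-fold higher (4.83 to 7.28). The vacuolar glutathione-conjugate transporters BPT1 and YCF1 were 3.26-fold and 2.15-fold higher. ECM38, the vacuolar gamma-glutamyl transpeptidase, was 2.36-fold higher and DUG2, a subunit of the cytosolic degradation complex, 3.77-fold higher. Its partner DUG1 was 2.23-fold lower (2.03 to 2.46), while DUG3 and the cyclotransferase gene GCG1 had ratios of 1.02 and 1.10. GEX1 and GEX2, glutathione exchangers below the RPKM minimum and near-identical to each other, had 33 and 12 reads in the wild type and 0 in Y518. GEX2 lies in a run of 4 neighbouring genes on chromosome XI without a read in Y518. Without the RPKM minimum, which lets in both genes, the list median was 0.61 at percentile 89.0 and no longer stood apart. After centring on all genes 4 members were higher and 1 lower, with ECM38 and YCF1 below 2-fold.

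**Figure D1:**
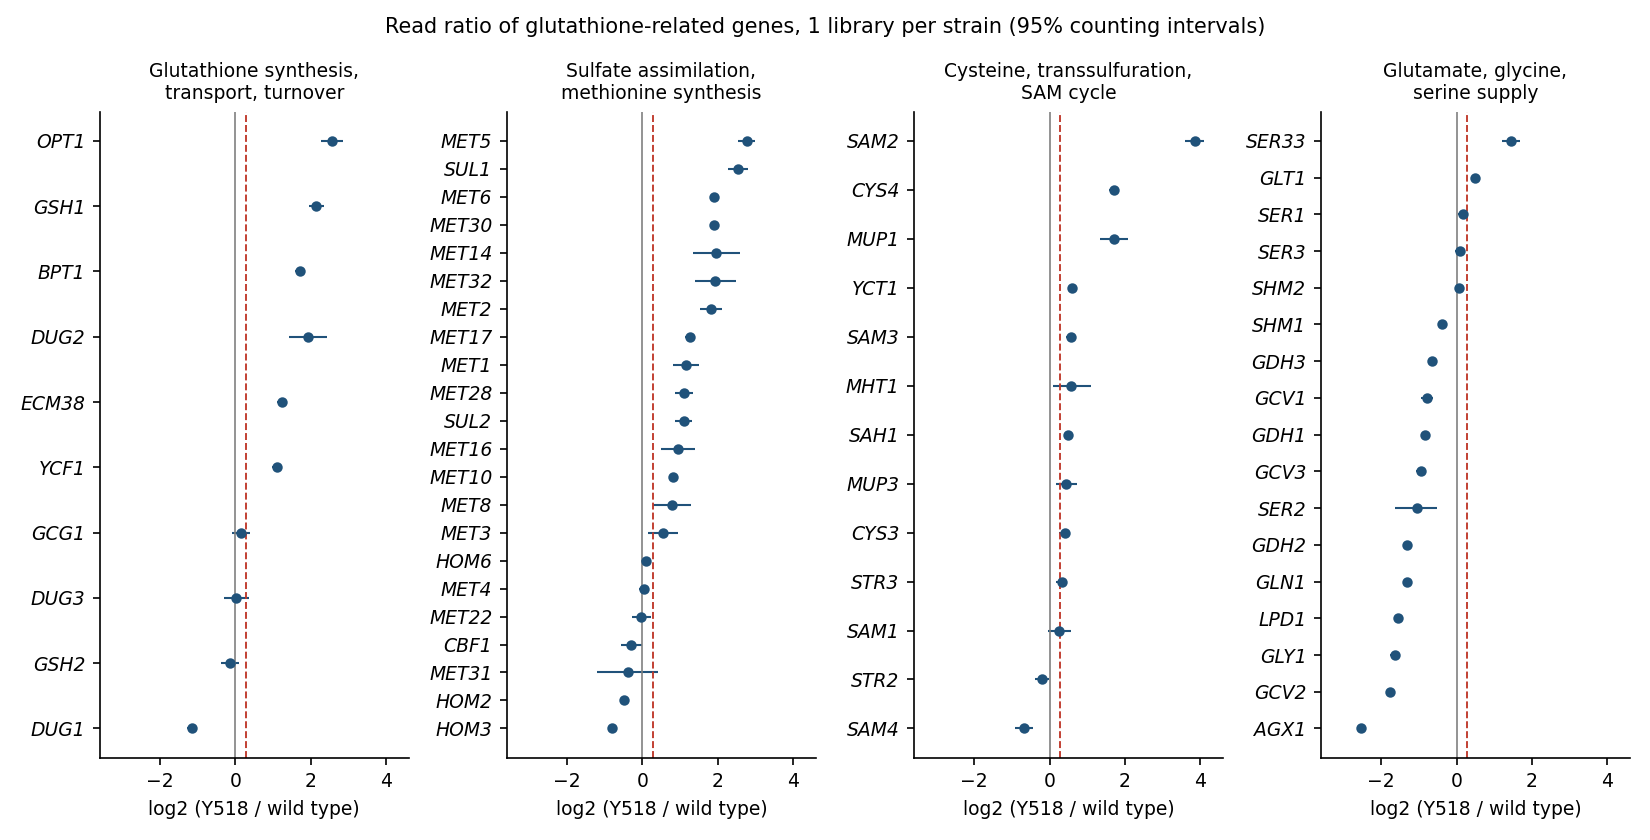
Each point is 1 gene's log2 ratio of reads per library total, Y518 over wild type (x axis), for the measured genes of 4 lists; bars are 95% counting intervals, the grey line marks 0 and the dashed red line the median of all genes (0.27). GSH1 lies at a 4.41-fold excess in Y518 while GSH2 lies close to 0, and most genes of the glutamate, glycine and serine list lie left of the lines.

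Sulfate assimilation and methionine synthesis, which supply reduced sulfur for cysteine, were also higher in Y518. Of 22 measured genes 11 were at least 2-fold higher, 0 were lower and 11 were within 2-fold. The median log2 ratio was 0.97, 0.70 above all genes, at percentile 99.98. MET5, a sulfite reductase subunit, was 6.80-fold higher on 180 reads in the wild type, and the sulfate permease gene SUL1 5.77-fold higher (4.84 to 6.92). MET6, methionine synthase, and MET30, encoding the ubiquitin ligase subunit that restrains Met4, were 3.76-fold and 3.73-fold higher. MET3, ATP sulfurylase, had a ratio of 1.47 and MET4, the transcriptional activator of the pathway, a ratio of 1.03. After centring, 7 genes were higher and 1 was lower. In the cysteine, transsulfuration and S-adenosylmethionine list 3 of 13 genes were higher and 0 lower, and its median of 0.50 did not stand apart (percentile 80.4). These were SAM2, S-adenosylmethionine synthetase (14.4-fold, 12.1 to 17.3), CYS4, cystathionine beta-synthase (3.25-fold), and the methionine permease gene MUP1 (3.29-fold). CYS3, cystathionine gamma-lyase, had a ratio of 1.33. SAM4, which shares a near-identical stretch with another gene, was 1.60-fold lower.

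The list of genes for glutamate, glycine and serine, which holds enzymes that make and enzymes that use these amino acids, was lower in Y518 as a group. Of 17 measured genes 6 were at least 2-fold lower, 1 was higher and 10 were within 2-fold (10 lower and 1 higher after centring), with a median log2 ratio of -0.84 (-1.11 relative to all genes) at percentile 0.04. AGX1, which makes glycine from glyoxylate, was 5.80-fold lower (5.56 to 6.06). The glycine cleavage genes GCV2 and LPD1 were 3.38-fold and 2.96-fold lower, and GLY1, threonine aldolase, 3.08-fold lower. GLN1, glutamine synthetase, which uses glutamate, and GDH2, the glutamate-degrading dehydrogenase, were 2.49-fold and 2.48-fold lower. The biosynthetic glutamate dehydrogenase gene GDH1 was 1.79-fold lower. SER33, of serine synthesis, was the higher gene at 2.73-fold.

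Enzymes that use glutathione did not stand apart as a list. Of 23 genes 9 were higher and 1 lower (7 and 3 after centring), with a median of 0.43 at percentile 78.6. SFA1, the glutathione-dependent formaldehyde dehydrogenase, was 10.8-fold higher (9.44 to 12.3) and GTT1, a glutathione transferase, 9.10-fold higher (8.20 to 10.1). GTO1 was 5.17-fold and the monothiol glutaredoxin gene GRX3 4.23-fold higher. GLR1, glutathione reductase, was 1.10-fold lower with an interval that included 1. The oxidative stress list outside glutathione had 7 of 22 genes higher and 3 lower (4 and 4 after centring), with a median of 0.27 at percentile 58.2. There the peroxiredoxin gene AHP1 was 7.90-fold and the superoxide dismutase gene SOD1 4.84-fold higher, whereas OYE2 was 6.97-fold and the thioredoxin reductase gene TRR1 2.85-fold lower. YAP1, encoding the main oxidative stress activator, had 202 RPKM in the wild type and 185 RPKM in Y518.

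Nuclear genes of respiration were lower in Y518. In the tricarboxylic acid cycle 13 of 17 genes were at least 2-fold lower and 1 was higher (14 and 0 after centring), with a median log2 ratio of -1.34 at percentile 0.02. All 4 succinate dehydrogenase genes were among them: SDH3 was 5.91-fold lower (5.65 to 6.18), SDH1 4.82-fold and SDH2 3.63-fold, and SDH4 had 6564 reads in the wild type and 1504 in Y518. The higher gene was CIT2, the peroxisomal citrate synthase, which was within 2-fold after centring. In the respiratory chain and ATP synthase 25 of 34 genes were lower and 3 higher (28 and 3 after centring), with a median of -1.56, and 0 of 10000 matched lists lay as low. NDI1, the internal NADH dehydrogenase, was 5.03-fold lower (4.76 to 5.31). The 3 higher genes were CYC7, the hypoxic cytochrome c (32.7-fold on 4 reads in the wild type, 12.5 to 122), the external NADH dehydrogenase gene NDE2 (6.83-fold) and COX5B, the hypoxic cytochrome oxidase subunit (5.30-fold), while its aerobic counterpart COX5A was 3.53-fold lower. Of the transcripts encoded in mitochondria, which were in no list and were picked after their values were seen, COX1 was 5.78-fold higher in Y518 (774 and 4103 reads) and ATP6 3.24-fold (40 and 119 reads). COX2, COB and COX3 were 14.0-fold, 7.09-fold and 4.18-fold higher on 6, 4 and 6 reads in the wild type, and OLI1 was 1.10-fold lower (8126 and 6763 reads). None of these transcripts was in the search for near-identical copies, and COX1 and ATP6 were covered over only 42.2% and 50.1% of their length in Y518, so their folds are uncertain. Of 56 mitochondrial ribosomal protein genes 15 were lower and 0 higher (25 and 0 after centring), with a median of -0.57 at percentile 0. MRPL7, MRPL32, MRPL35 and MRPS9 were 3.10-fold, 3.16-fold, 2.91-fold and 2.74-fold lower.

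Glycolytic genes showed a mixed picture. Of 17 genes 7 were higher and 1 lower, with a median of 0.87 at percentile 94.9, inside the limits. The pyruvate kinase gene CDC19 was 9.24-fold higher (8.87 to 9.63) and HXK2 7.56-fold higher, while HXK1, the other hexokinase gene, was 8.99-fold lower (8.67 to 9.34). In ethanol and acetate metabolism 5 of 16 genes were higher and 1 lower, or 4 and 4 after centring (median 0.17, percentile 42.0), with the minor pyruvate decarboxylase genes PDC5 and PDC6 22.3-fold and 14.6-fold higher and PDC1 1.12-fold lower. Of 14 pentose phosphate and NADPH genes 5 were higher and 0 lower, or 4 and 3 after centring (median 0.14, percentile 39.0). There SOL4 was 21.5-fold and GND2 5.23-fold higher, whereas ZWF1, the first enzyme, had a ratio of 1.08. Gluconeogenesis and the glyoxylate cycle had 3 of 15 genes higher and 3 lower, or 3 and 4 after centring (median 0.01, percentile 27.2), with PCK1 2.35-fold lower. In trehalose and glycogen metabolism 1 of 17 genes was higher and 4 were lower, or 1 and 5 after centring (median -0.14, percentile 9.46), with glycogen phosphorylase GPH1 4.94-fold lower. Hexose transporters and sugar-use genes stood below matched lists, with 7 of 20 genes lower and 4 higher, or 9 and 3 after centring (median -0.45, percentile 0.22). Beside HXT6 and HXT4, STL1, a glycerol transporter gene, was 11.2-fold and HXT3 7.66-fold lower, and HXT5 was 5.23-fold higher. This list did not stand apart without the RPKM minimum (median -0.08, percentile 5.76) or without the genes of chromosome IX (median -0.22, percentile 3.24).

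Cytosolic ribosomal protein genes were higher in Y518. Of 138 genes 118 were at least 2-fold higher in Y518 and 0 lower, and 99 remained at least 2-fold higher after centring. The median log2 ratio was 1.53, 1.26 above all genes, and all 10000 matched lists lay below it. RPL43B was 6.72-fold and RPP2A 5.64-fold higher. RPL20B was 17.3-fold higher (14.0 to 21.7), but was covered over only 49.1% of its length in the wild type, so its fold is uncertain. Of these genes 38 have near-identical copies. Ribosome biogenesis genes had a median of 0.60 with 6 of 32 higher and 0 lower (3 and 0 after centring), at percentile 96.9, just inside the limit. Proteasome genes had a median of 0.60 at percentile 98.0, with 5 of 32 higher and 0 lower (2 and 0 after centring). RPT4, PRE6, RPN1 and PRE10 were 2.78-fold, 2.48-fold, 2.23-fold and 2.21-fold higher, and after centring RPN1 and PRE10 were below 2-fold. Autophagy and vacuolar protease genes had a median of 0.92 at percentile 99.8, with 9 of 23 higher and 0 lower (4 higher after centring). Of the list's members, APE3, YPS3, ATG5 and CPS1 were 3.08-fold, 3.10-fold, 2.82-fold and 2.59-fold higher, YPS3 being a cell-surface rather than a vacuolar protease gene. Cell cycle genes moved the other way, with 7 of 26 lower and 1 higher (9 and 1 after centring) and a median of -0.58 at percentile 0. The cyclin genes PCL1 and CLN1 were 5.95-fold and 2.76-fold lower, CTS1, a daughter-cell chitinase, 2.83-fold lower, and POL30, the replication clamp, 3.88-fold higher.

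**Figure D2:**
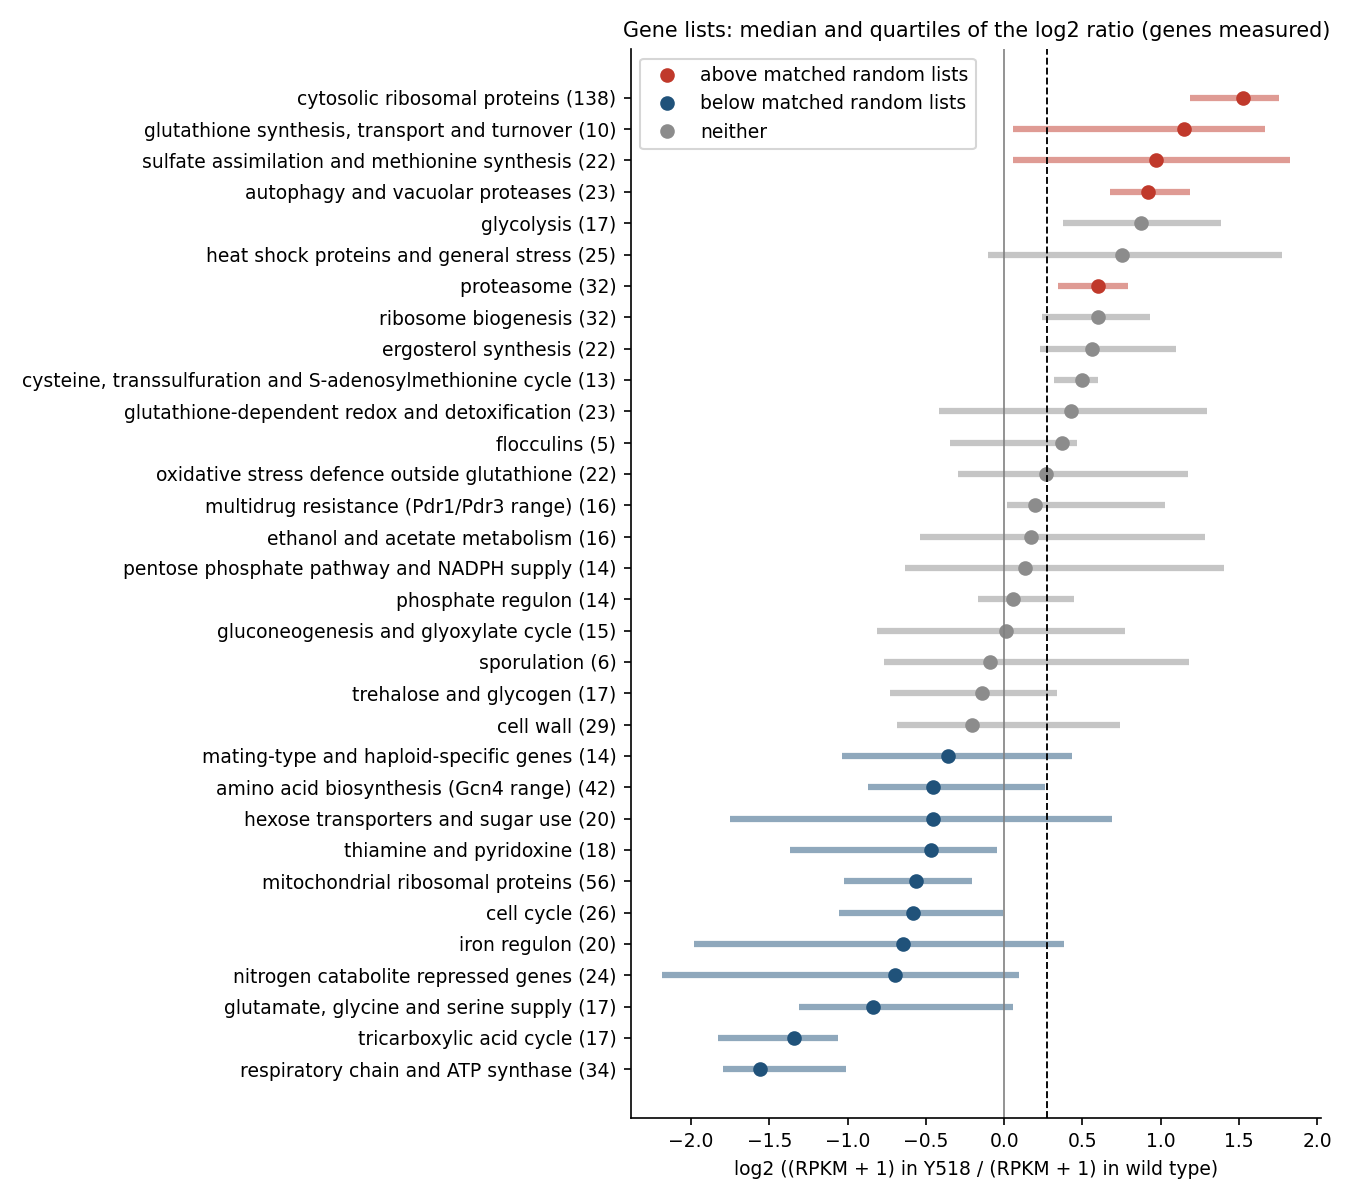
Points show each list's median log2 ratio of (RPKM + 1), Y518 over wild type (x axis), and bars its quartiles, with the number of measured genes in brackets; red and blue mark lists above and below matched random lists. The dashed line is the median of all genes (0.27). Cytosolic ribosomal proteins lie highest (1.53) and the respiratory chain lowest (-1.56), with 5 lists above and 11 below matched random lists.

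Nutrient-regulated lists were mostly lower in Y518. Of 24 nitrogen catabolite repressed genes 10 were lower and 3 higher, or 12 and 2 after centring (median -0.70, percentile 0). Beside AGP1, the allantoate transporter gene DAL5 was 12.9-fold and the GABA permease gene UGA4 6.85-fold lower. PUT1, proline oxidase, was 25.9-fold higher (23.4 to 28.8). Of 42 amino acid biosynthesis genes 7 were lower and 5 higher, or 13 and 2 after centring (median -0.45, percentile 0.05), with ARG1 4.80-fold, TRP4 3.79-fold and TRP3 2.96-fold lower and LYS12 4.65-fold higher. In the iron regulon 8 of 20 genes were lower and 2 higher, or 10 and 1 after centring (median -0.65, percentile 0.11). Beside FIT2 and FIT3, which lie in a stretch of chromosome XV with almost no reads in Y518, FRE3, which borders that stretch, was 6.18-fold and ARN2 5.34-fold lower, FET3, the ferroxidase gene, 1.78-fold lower and the haem oxygenase gene HMX1 3.80-fold higher. Without the genes of that stretch the list's median was -0.42. No percentile is given for that median, so it does not show whether the list still stood apart. Thiamine and pyridoxine genes had 6 of 18 lower and 0 higher, or 8 and 0 after centring (median -0.47, percentile 0.08). THI4 was 3.31-fold lower, while SNZ2, SNO3 (77 reads against 0, at least 23.5-fold lower) and SNZ3 (7.03-fold lower) have near-identical copies. Without such genes the median was -0.24 at percentile 2.55 and the list no longer stood apart. The phosphate regulon had 2 of 14 genes higher and 1 lower, or 2 and 2 after centring (median 0.06, percentile 21.4).

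Markers of mating type and sporulation, which describe the cells a culture could hold, had few reads for most members. Mating-type and haploid-specific genes had 4 of 14 lower and 1 higher, or 4 and 0 after centring (median -0.36, percentile 0.32). Beside MF(ALPHA)1, STE6 was 2.58-fold lower, STE18 had 17 reads against 5 and MFA2 8 against 3, the last with an interval of 0.59 to 14.3. The receptor genes STE2 and STE3 had 43 and 29 reads in the wild type and 30 and 61 in Y518. With a pseudocount of 5 RPKM, STE6, STE18 and MFA2 were below 2-fold. Sporulation genes had 2 of 6 higher and 0 lower, or 2 and 2 after centring (median -0.09, percentile 16.5), SPS100 being one of them. Heat shock and general stress genes had 11 of 25 higher and 2 lower, with a median of 0.75 at percentile 96.6. SSA3 was 22.7-fold, HSP12 15.9-fold and HSP26 4.26-fold higher, whereas MSN4, encoding a stress activator, was 8.77-fold and HSP30 3.89-fold lower. Cell wall genes had 6 of 29 higher and 3 lower, or 5 and 6 after centring (median -0.20, percentile 3.51), and flocculins 1 of 5 higher and 1 lower (median 0.37, percentile 48.9). Ergosterol genes had 8 of 22 higher and 1 lower, or 4 and 2 after centring (median 0.56, percentile 92.0), with HMG1 7.06-fold and ERG24 6.91-fold higher. Multidrug resistance genes had 4 of 16 higher and 1 lower, or 4 and 2 after centring (median 0.20, percentile 45.8).

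The differences were not spread evenly over the genome. The median log2 ratio of the 196 measured genes of chromosome IX was 1.01, against medians between -0.11 and 0.41 on the other nuclear chromosomes. On chromosome IX 100 genes (51.0%) were at least 2-fold higher in Y518, compared with 969 of 5208 genes (18.6%) on the other nuclear chromosomes. Its left and right arms had medians of 1.02 and 0.93. Without chromosome IX, but with the genes not placed on a nuclear chromosome, 976 genes were at least 2-fold higher and 471 lower. Chromosomes V, VII and XVI had medians of -0.11, 0.05 and 0.08, each lower than all 10000 matched sets of genes. On chromosome IX lie GTT1, MET30, MET28, SER33, COX5B and LYS12 of the lists above and EMA17. None of the 10 measured members of the list of glutathione synthesis, transport and turnover lies there. On chromosome XV, 7 neighbouring genes from YOR381W-A to YOR387C, FIT2, FIT3, FRE5 and PHR1 among them, had 70421 reads in the wild type and 6 in Y518. The flanking genes FRE3 and FDH1 were lower too, with 147 and 296 reads in Y518 where 909 and 798 would be expected from the wild type. The next genes outward, RDR1 and YOR389W (which has a near-identical copy), had 171 and 321 reads where 186 and 309 would be expected. FRE3 was covered over 67.0% of its length in Y518 and 99.7% in the wild type. Other runs without a read in Y518 were YOL165C to YOL162W (5 genes with BDS1, 586 reads in the wild type), YKR103W to YKR106W (4 genes with GEX2, 234 reads) and YOL159C-A to YOL158C (3 genes, 62 reads). In the wild type, 3 genes from YHR214C-D to YHR215W had 2 reads against 70 in Y518, and the pair YHR021W-A and YHR022C had 3 against 84. Loss of reads to near-identical copies was not examined for the runs outside the stretch of 7 genes, and GEX2 has such a copy.

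**Figure D3:**
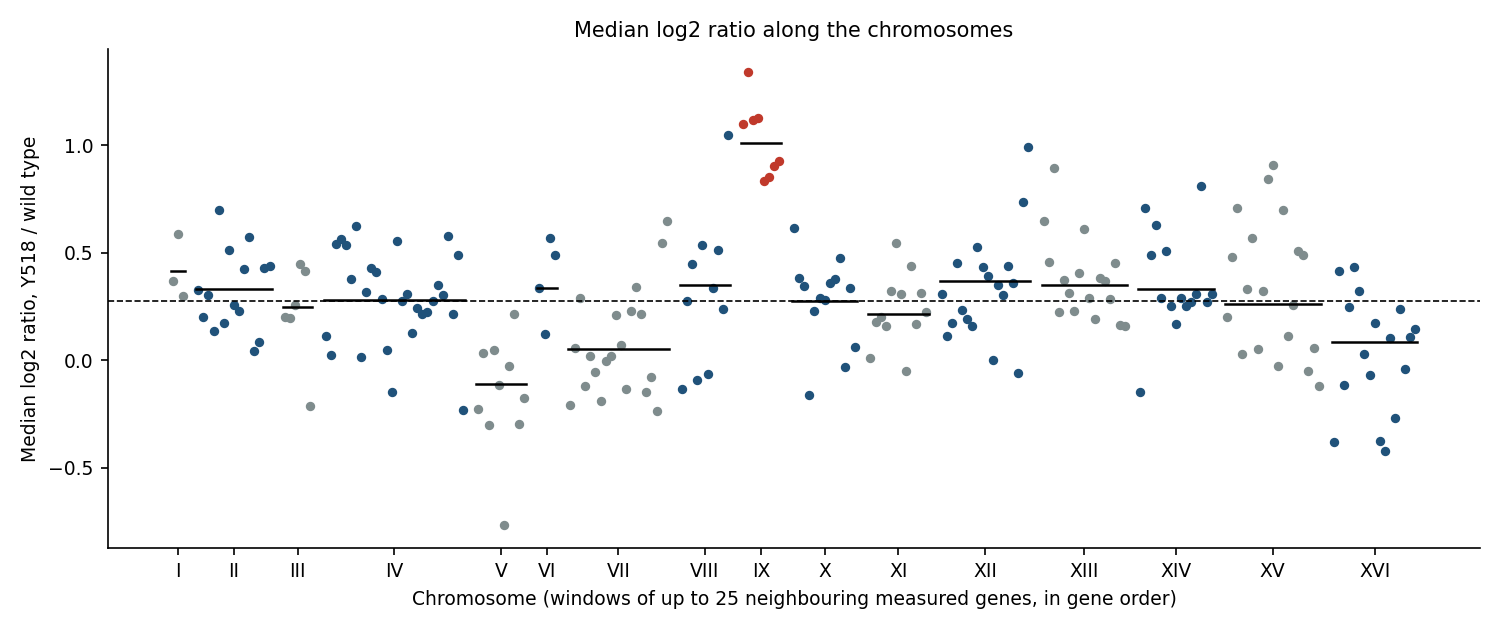
Each point is the median log2 ratio (y axis, Y518 over wild type) of up to 25 neighbouring measured genes in gene order along the 16 nuclear chromosomes (x axis); black bars are chromosome medians and the dashed line the median of all genes (0.27). The 8 windows of chromosome IX (red) lie between 0.83 and 1.34, and the 10 windows of chromosome V all lie below the dashed line.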

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

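All counts kept within 1.5 times of the reported 1076 higher and 481 lower genes under 0.1 and 5 RPKM pseudocounts, no filter, a mean of at least 20 RPKM, TMM scaling and CPM. The exceptions were centring on the median of all genes, which gave 714 higher and 737 lower genes, and the demand that both counting bounds lie beyond 2-fold, which left 715 higher and 342 lower (the latter within 1.5 times). TMM and centring moved the median of all genes by -0.26 and -0.27, and the share of higher genes among all calls from 69.1% to 50.6% and 49.2%. Centring moves a list and its random lists alike, so it cannot change a percentile, and TMM is close to such a shift. With no filter on low values, the list of glutathione synthesis, transport and turnover had a median of 0.61 at percentile 89.0. This is because GEX1 and GEX2 then enter with 0 reads in Y518. The list stood apart under the other alternatives that could move its percentile (99.1 with a mean of at least 20 RPKM to 99.9 on the shorter table). None of those alternatives admits GEX1 or GEX2, so they do not test the list with these genes. None of the list medians that stood apart changed sign. Lists with medians between 0 and 0.27 (oxidative stress, ethanol, pentose phosphate, gluconeogenesis, phosphate, multidrug) take a negative sign when centred. Ribosome biogenesis crossed the upper limit under 5 alternatives, for example to percentile 98.7 with a mean of at least 20 RPKM. Heat shock genes crossed it without genes that have near-identical copies (median 1.02, percentile 99.5) and without chromosome IX (percentile 97.6). The cell wall list fell to percentile 2.26 on the 5080 genes of the shorter table. That table, the removal of near-identical copies and the removal of chromosome IX were chosen after seeing the data, and gave 888, 1019 and 976 higher and 463, 466 and 471 lower genes. A comparison with the shorter table as a source of other values was not run, because its values are the same. Small lists with under 5 genes left in it, without copies, without chromosome IX or at a mean of at least 20 RPKM gave no value there. The flocculin median was 0.01 without a filter and the sporulation median -0.66 without chromosome IX. No paired analysis was possible because each strain has 1 library, and no library could be left out. Depth limits statements on genes near the floor, such as MFA2, whose counting interval includes 1.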

Other observations

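Tests of the spread of ratios on chromosome IX, of gene length and GC content, and of ribosomal protein genes without near-identical copies were written before their values were seen. The other tests in this part were chosen after the results were seen.

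Some genes outside the fixed lists were picked because of their values, among them genes of lipid synthesis, and they do not stand for their pathways. INO1, inositol-3-phosphate synthase, had 95.1 RPKM in the wild type and 3398 in Y518, a 35.7-fold excess (95% counting interval 33.2 to 38.6). OPI3 and CHO2, S-adenosylmethionine-dependent methyltransferases of the route from phosphatidylethanolamine to phosphatidylcholine, were 13.3-fold and 4.03-fold higher. CHO1, phosphatidylserine synthase, was 3.03-fold higher, and the inositol transporter gene ITR1 5.12-fold. The fatty acid synthase genes FAS1 and FAS2 were 2.79-fold and 2.77-fold higher, the desaturase gene OLE1 2.90-fold, and the carboxylase gene ACC1 2.22-fold. ACC1 falls below 2-fold once ratios are centred. POT1, the peroxisomal thiolase, was 16.0-fold higher. The plasma membrane proton pump gene PMA1 was 3.14-fold lower and its minor paralogue PMA2 15.3-fold higher. The arsenic resistance genes ARR2 and ARR3 had 142 and 289 reads in Y518 against 3 and 5 in the wild type.

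The stretch of 7 neighbouring genes on chromosome XV had 6 reads in Y518 where 64570 would be expected from the wild type. Loss of reads to near-identical copies is argued against, since 0 of the 7 genes have such a copy and those with at least 100 reads were covered over at least 97.6% of their length in the wild type. Lower transcription of the iron regulon stays open: PHR1 and YOR385W, which the iron list did not hold, had 0% of the 465 reads expected, but they belong to the run by their lack of reads, and the other iron genes had a median log2 ratio of -0.42. It also stays open that the segment may be missing from Y518 or too diverged from the reference to be counted. The length of the run does not decide between these, since its 7 genes were found by their lack of reads, and DNA was not measured.

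The median ratio of Y518 to wild type on chromosome IX was 1.66 times that of all genes. A few strongly changed genes do not account for this, since they could hardly move a median of 196 genes. The lower part of the distribution was shifted too, with the 25th percentile of the log2 ratio 0.74 above that of the other genes. Gene length and GC content do not account for the shift either, since the chromosome median lay 0.41 above the highest of 10000 sets matched on both. A candidate explanation is extra copies of the whole chromosome in Y518, which needs a shift along both arms. On chromosome IX 8 of 8 windows lay over 0.4 above the median of all genes, against 11 of 207 windows elsewhere. Chromosome IX was picked by its high median, so that contrast was largely fixed in advance and is no separate support. The windows show only that the shift was not confined to a part of the chromosome. A ratio between the strains cannot tell extra copies in Y518 from fewer copies in the wild type. The shift is a hypothesis from RNA of 1 library per strain, and the smaller deficits of chromosomes V, VII and XVI (-0.38, -0.22 and -0.19 relative to all genes) were not weighed.

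Cytosolic ribosomal protein genes were higher while nuclear respiratory genes were lower in Y518. Scaling to total reads does not account for it, as the ribosomal list lay 1.26 above the median of all genes and the 51 respiratory and citrate cycle genes at -1.80 relative to it. Nor do length and GC content, with the ribosomal list 0.71 above the highest and the respiratory genes -1.13 from the lowest matched set, nor shared reads, with 100 ribosomal genes free of near-identical copies 1.27 above all genes. Faster growth of the Y518 culture at harvest would raise ribosome biogenesis and cell cycle genes too: the cell cycle list, at percentile 0, argues against it as the whole cause, while ribosome biogenesis, at 96.9 and above the limit under 5 alternatives (up to 98.7), goes with it. A difference between the strains in growth, growth stage or oxygen supply at 24 h may still underlie the pattern, and with 1 culture per strain at 1 time point it stays open and untested.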
